A study of Mus musculus with 9 samples.

How the data were processed

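Messenger RNA was profiled in 9 libraries from mouse embryonic stem cells of the V6.5 line. Per the labels' protocols, 600 ng of total RNA, extracted with Trizol, entered the forward version of Lexogen's QuantSeq kit. This kit makes stranded libraries from the 3' ends of polyadenylated transcripts, so that 1 read stands for about 1 fragment near the end of a transcript and gene length plays little part in the counts. The labels name 4 wild-type (WT) libraries and 5 labelled as lacking both KLF2 and KLF4 (DKO), all grown with 15% FBS, LIF and 2 inhibitors (of GSK and MEK). The labels do not say that the replicates came from separate cultures or clones. P-values of single genes and of measures per library therefore reflect only the spread between these samples, which may be technical. The tests of gene lists and the scan along chromosomes compare genes with other genes, and their p-values do not measure the spread between cultures either.

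The authors deposited whole-number exon read counts per gene for 9 libraries, not normalized. Per the submitters' processing notes the build was mm10 and the tools were cutadapt, STAR, featureCounts and DESeq2, with no versions, roles or order. The annotation release, the strand setting of the counting, and the handling of multi-mapped and duplicate reads are not given in the sources used here. Reads of near-identical gene copies and of overlapping or antisense genes may therefore be split, lost or shared, and such genes are named as uncertain. The table held 52550 Ensembl gene identifiers, of which 52403 were matched by identifier to GENCODE mouse release 21 on the same build and 147 were not. Symbols, positions and chromosomes come from that annotation. Every column of the table was used.

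Library totals ran from 6035642 to 7098530 counts. A floor of 3 counts in 1 library corresponded to 0.423 to 0.497 CPM, counts scaled to a library's total, and intervals and floors cover counting error only, since no molecular identifiers were described. Before replicates were averaged, each of the 16 pairs of libraries within a group was compared by a chi-square test of its counts. The chi-square per degree of freedom lay between 2.31 and 5.40, so no pair looked like 1 library counted in duplicate.

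Genes were kept with edgeR's filterByExpr by group, scaled by TMM factors, and tested with the robust quasi-likelihood fit and test of edgeR 4.0.16 in R 4.3.3, on all 9 libraries with the genotype label as the only term. P-values were adjusted by the Benjamini-Hochberg (BH) method, and an adjusted p under 0.05 counts as passing. Fold changes are log2 of DKO over WT with a standard error (SE) taken from the fold change and its F statistic. CPM values are means ± SD on TMM-scaled library sizes. Single measures per library were compared with exact permutation tests, 2-sided, over the 126 ways of dividing 9 libraries into 4 and 5. The smallest p these can give is 0.00794.

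There were 26 gene lists, covering pluripotency states, epithelial and mesenchymal genes, fibroblast markers of the kind feeder cells express, lineages, the KLF and SP family, signalling responses, DNA methylation, imprinting, metabolism, stress, the cell cycle and ribosomal proteins. Of these, 24 had at least 5 tested members and were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and BH adjustment over the lists. The test was repeated with the correlation estimated from the data. No list passed in that form, so no list call holds under it. The estimated correlation was below the preset for naive pluripotency (-0.005) and mesendoderm (-0.081), yet their unadjusted camera p rose. It went from 0.00864 to 0.0246 and from 0.0026 to 0.0169, so a higher correlation is not what raised these p-values. Fry, another limma test, asks whether a list's genes move on balance one way and does not compare them with other genes. Lists share a few members.

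Named genes followed a rule. Klf2, Klf4 and the 3 Grhl genes were always named. So were the 12 largest rises and 12 largest falls among genes that passed, reached a mean of 10 CPM in a group and did not overlap between the groups, leaving out predicted genes without a name. Of each list, up to 6 passing members with the smallest adjusted p and up to 2 members of at least 50 CPM that did not pass were named. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. A few further members are named because 5 or fewer of a list moved one way, and these were picked after their values were seen. Some genes that the rule took are not reported here.

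Median log2 fold changes per chromosome were compared between groups, with a shift of 0.2 or more counted. After the data were seen, each chromosome was also scanned for 1 change point in log2 fold change along gene order, with fold changes limited to 1.5 either way, at least 20 genes on each side and 1000 permutations of gene order. The position of the chromosome 8 step was given a 95% bootstrap interval. Fits without chromosomes 8 and Y, or 6, 8 and Y, were also added after the data were seen.

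The alternatives were other scalings, no filter and a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, thinning to the smallest library, each library left out in turn, and the replicate number as a block. The gene test, the list test and the scan were tested on simulated counts for 11865 genes in the real design. The gene test called 24.5% of genes changed 1.25-fold, 89.8% of those changed 1.5-fold and 100% of those changed 2-fold. Of its calls, 5.11% were unchanged genes. The spread between libraries beyond counting error, as a coefficient of variation, was 6.56% in the data. The simulation set a larger one and changed fewer genes than were called in the data, so these shares may not hold for the data. The list test passed the shifted list and 0 of 24 unchanged lists, and the scan found the planted step at its exact place and 0 steps on other chromosomes. The simulated genes were drawn independently of each other, so these results do not cover lists or neighbouring genes that vary together.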

Results

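Transcript levels were measured in mouse embryonic stem cells from V6.5, a hybrid line, held in naive pluripotency by LIF and inhibitors of GSK and MEK (2i). The comparison was between 4 libraries labelled WT and 5 labelled as lacking the transcription factors KLF2 and KLF4 (DKO), in a series whose title concerns GRHL2 and enhancer use as cells leave naive pluripotency. Library totals were 6811200 ± 225900 counts in WT and 6296800 ± 236600 in DKO (SD, n = 4 and 5, exact permutation p = 0.0238, BH 0.0298 over 5 library measures). Genes with at least 1 count numbered 18268 ± 146 in WT and 18010 ± 107 in DKO (exact p = 0.00794, BH 0.0132). Across genes, which are not independent, r was 0.989 to 0.990 within WT, 0.985 to 0.989 within DKO and 0.945 to 0.955 between the groups. The first principal component held 69.2% of the variance and separated the groups, and the next, at 6.11%, spread the libraries labelled DKO, with DKO 3 at 23.1, DKO 1 and 2 at 6.22 and 1.16 and DKO 4 and 5 at -13.5 and -14.0.

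Klf2 and Klf4, the genes named by the knockout, had more reads in the libraries labelled DKO than in WT. Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656, plus strand) had 3042, 3064, 3048 and 3297 counts in WT 1 to 4 and 3970, 3822, 3750, 3750 and 4044 in DKO 1 to 5. Its level was 459.6 ± 9.87 CPM in WT and 615 ± 19 in the libraries labelled DKO, a log2 fold change of 0.42 ± 0.04 (SE, edgeR adjusted p = 6.2e-10). Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466, minus strand) had 5860, 5085, 5873 and 6183 counts in WT 1 to 4 and 9385, 10210, 10778, 9937 and 9722 in DKO 1 to 5. It stood at 848 ± 49.1 CPM in WT and 1595 ± 140 in the libraries labelled DKO, a log2 fold change of 0.91 ± 0.06 (SE, edgeR adjusted p = 8.6e-14). These counts go against the knockout label. The labels do not give the deleted part of either gene, and reads at a 3' end outside that part check nothing, so every direction in the results is that of the libraries labelled DKO over those labelled WT.

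**Figure D1:**
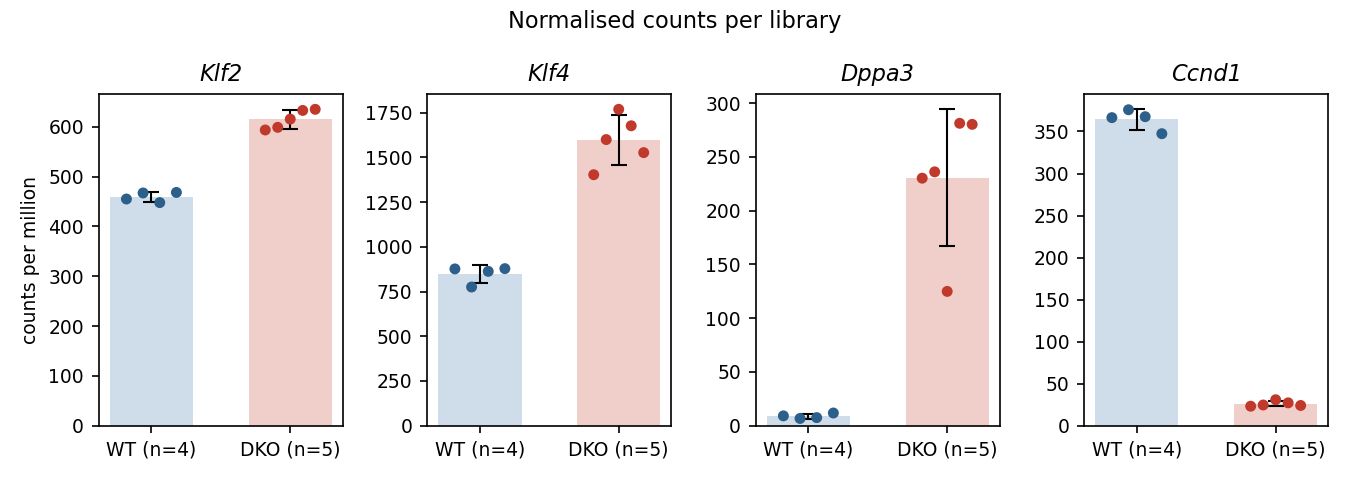
Expression in CPM of Klf2, Klf4, Dppa3 and Ccnd1 in the 4 WT libraries and the 5 libraries labelled DKO, with bars for the means, error bars for the SD and a point per library. Klf2 and Klf4 are higher in all 5 libraries labelled DKO than in any WT library, Dppa3 rises from 8.78 to 231 CPM and Ccnd1 falls from 364 to 26.0 CPM.

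Among the genes with the largest rises were Dppa3, a maternal factor of naive cells and the germ line, the myelin genes Mbp and Mobp, and Sox21, a transcription factor of neural cells. Dppa3 went from 8.78 ± 2.24 to 231 ± 63.7 CPM (log2 fold change 4.71 ± 0.35, edgeR adjusted p = 1.2e-05), with DKO 3 the lowest of the libraries labelled DKO at 761 counts against 1507 to 1785 in the other 4. Mbp rose by a log2 fold change of 3.74, Mobp by 3.85 and Sox21 by 3.31. Ccnd1, which encodes cyclin D1, fell from 364 ± 12 to 26.0 ± 3.11 CPM (log2 fold change -3.81 ± 0.07, edgeR adjusted p = 2.1e-31). Id1, a target of BMP signalling, fell from 67.3 ± 3.44 to 5.64 ± 0.855 CPM.

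The other large rises were Lrtm2 (4.84), Lipc (4.41), Rhox9 (4.03), H2-Bl (4.02), Klhdc7a (3.63), Zmat4 (3.42), Lrrn4 (3.35) and Rps6kl1 (3.27), given as log2 fold changes. The other large falls were Ddx3y (-5.12), Npr3 (-4.92), Pramel7 (-4.91), Crxos (-4.45), Emp1 (-4.20), Liph (-4.17), AA467197 (-4.12), Klk10 (-4.04), Fgf10 (-3.78) and Ccdc141 (-3.75). Some of these sizes rest on few reads in the lower group. Lrtm2 (0.55 CPM), Lipc (0.59), Klhdc7a (0.82) and H2-Bl (0.84) lay near the floor in WT. Pramel7 (0.64), Npr3 (0.69), Ddx3y (0.74) and Fgf10 (0.93) did so in the libraries labelled DKO. Of 11893 genes tested, 2837 rose and 2852 fell in the libraries labelled DKO, or 47.8% together, and the smallest called log2 change was 0.104 in size. At least 2-fold changes numbered 492 up and 720 down. The H2-Bl, Rhox9 and Pramel7 families hold close copies, and Crxos is named for its place opposite another gene, so their counts are uncertain. Lrtm2, Dppa3 and Emp1 lie on the distal part of chromosome 6, where the median log2 fold change of edgeR, relative to genes off chromosomes 6, 8, Y and the mitochondrial genome, was 0.34, and Zmat4 on the proximal part of chromosome 8, where it was 0.41.

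**Figure D2:**
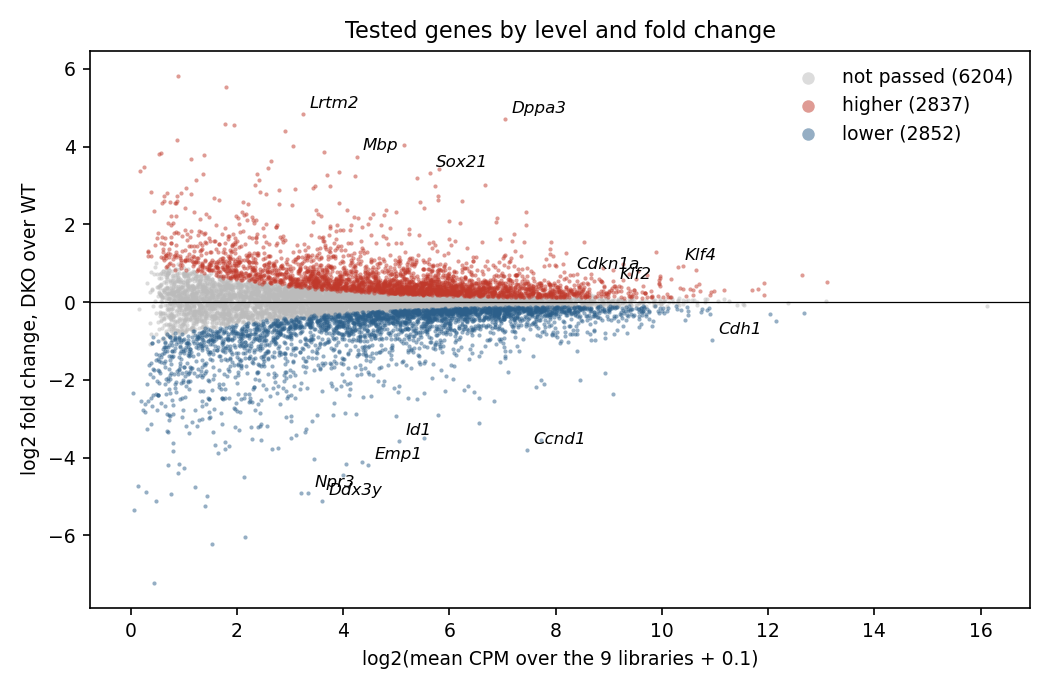
Log2 fold change of the libraries labelled DKO over WT against log2 of mean CPM (plus 0.1), a point per tested gene, red for the 2837 that were higher, blue for the 2852 that were lower and grey for those that did not pass, with some genes named. Changes of both signs occur from low to high levels, and Ccnd1 and Dppa3 stand out among the abundant genes.

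Genes of naive pluripotency, the state of the early epiblast, were on balance higher in the libraries labelled DKO. Dppa3, the nuclear receptor Nr0b1 and the homeobox gene Gbx2 rose, as did Klf5, a relative of the knockout targets, while Spic, an ETS factor, fell. Klf5 went from 164 ± 18.4 to 398 ± 71.4 CPM, Tfcp2l1, a LIF-responsive factor, from 799.9 ± 8.59 to 1127 ± 42.4, and Nr0b1 from 28.0 ± 0.622 to 59.2 ± 7.79. Of 19 tested members 11 rose and 5 fell (Spic, Tet2, Pecam1, Fgf4 and Zfp42), the same counts as when adjusted over the list alone, 11 and 5, and Jam2 (0.06) and Nr5a2 (-0.03) did not pass. The list passed camera upward (adjusted p = 0.0345, and adjusted p = 0.156 with an estimated correlation). Its adjusted p was 0.0605 without chromosomes 6, 8 and Y, a fit chosen after the data were seen, 0.0730 with the filter of 5 CPM in 4 libraries, 0.0530 without WT 2 and 0.04997 without WT 1, just under the limit, within a range of 0.0106 to 0.156 over 15 other camera fits. Dppa3 and Nanog (0.22) lie on distal chromosome 6.

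General pluripotency genes went both ways. Sox2 (0.72), Dppa5a (0.97) and Mybl2 (0.42) rose, while Lin28a (-1.14), an RNA-binding protein, and the Nodal co-receptor Tdgf1 (-0.82) fell, all as log2 fold changes. Of 17 tested members 8 rose and 6 fell, also 8 and 6 adjusted over the list alone, and camera did not pass (adjusted p = 0.532, with a median of -0.03 but a mean of 0.06 and an upward test). Rif1 (-0.03) did not pass. In the formative and primed list, the methyltransferase cofactor Dnmt3l fell from 986 ± 41.1 to 189.8 ± 25 CPM, and Tcf15 (-3.27), Sox4 (-2.28) and Foxd3 (-0.55) fell, while Zic2 (1.2), Zic5 (0.72) and Lef1 (3.0) rose. Of its 17 tested members 5 rose and 8 fell, and 5 and 9 adjusted over the list alone, with a camera adjusted p of 0.147.

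**Figure D3:**
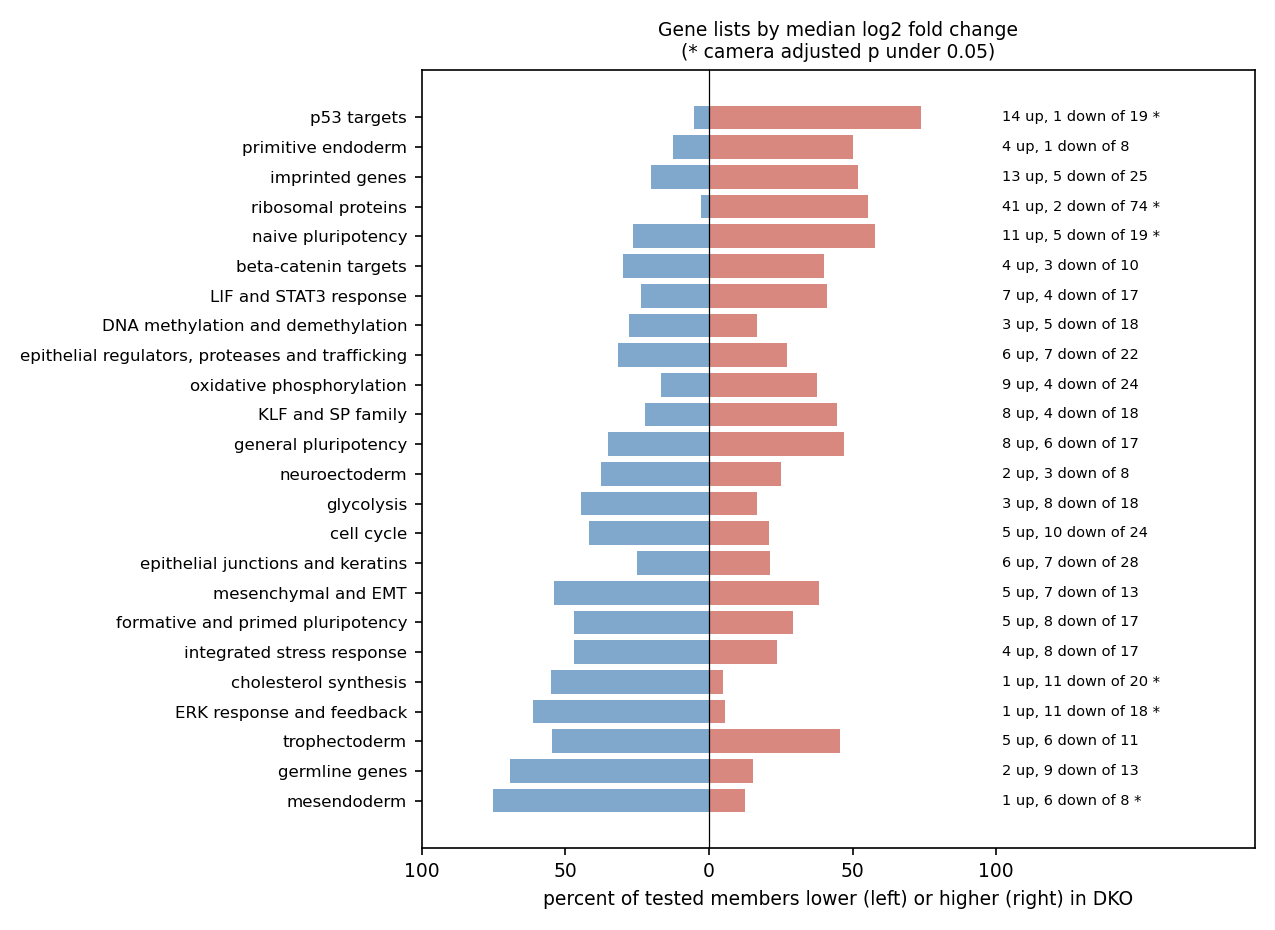
Percent of the tested members of each gene list that were lower (blue, left) or higher (red, right) in the libraries labelled DKO over WT, with lists ordered by median log2 fold change and asterisks on those past camera's adjusted p of 0.05. Lists with asterisks are p53 targets (14 up, 1 down of 19), ribosomal proteins and naive pluripotency upward, and mesendoderm (1 up, 6 down of 8), ERK response and cholesterol synthesis downward.

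Of genes that respond to ERK signalling, which the MEK inhibitor blocks in both groups, more fell than rose in the libraries labelled DKO. Ccnd1 fell, as did Spry4 (log2 fold change -3.87, from 6.32 to 0.417 CPM) and Spry2 (-0.43), feedback inhibitors of receptor tyrosine kinases, and Dusp5 (-1.30), an ERK phosphatase, with Phlda1 (-0.96) and Ier2 (-0.47). Of 18 tested members 1 rose (Etv5, 0.27) and 11 fell, and 2 and 11 adjusted over the list alone, while Il17rd (0.11) did not pass. The list passed camera downward (adjusted p = 0.00969, and adjusted p = 0.156 with an estimated correlation, in a range of 0.00654 to 0.156 over the other camera fits). Ier2 lies on distal chromosome 8, where the median was -0.61.

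The LIF and STAT3 list held rises of Ifitm3 (0.68), Socs2 (0.80), Tfcp2l1 (0.49) and Gbx2 (1.2) and falls of the kinases Pim1 (-0.48) and Pim3 (-0.50), while Stat3 (0.01) and Mcl1 (0.05) did not pass. Of 17 tested members 7 rose and 4 fell, also 7 and 4 adjusted over the list alone (camera adjusted p = 0.247). Of the beta-catenin targets, Lef1, Axin2 (0.66), Znrf3 (0.37) and Sp5 (0.54) rose and Ccnd1, Ascl2 (-1.50) and Tcf7 (-0.26) fell, while Sfrp1 (0.07) did not pass. Of 10 tested members 4 rose and 3 fell, and 5 and 3 adjusted over the list alone, with a camera adjusted p of 0.853 and a median (0.19) whose sign is not that of the mean. In the KLF and SP family, Klf5, Klf6 (0.48), Sp2 (0.57) and Sp5 rose beside Klf2 and Klf4, and Klf3 (-0.90), Klf8 (-0.76), Sp6 (-1.11) and Klf15 (-0.48) fell, while Sp1 (0.06) and Klf13 (-0.09) did not pass. Of 18 tested members 8 rose and 4 fell, and 8 and 5 adjusted over the list alone (camera adjusted p = 0.712, upward with a mean of -0.01 and a median of 0.06).

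**Figure D4:**
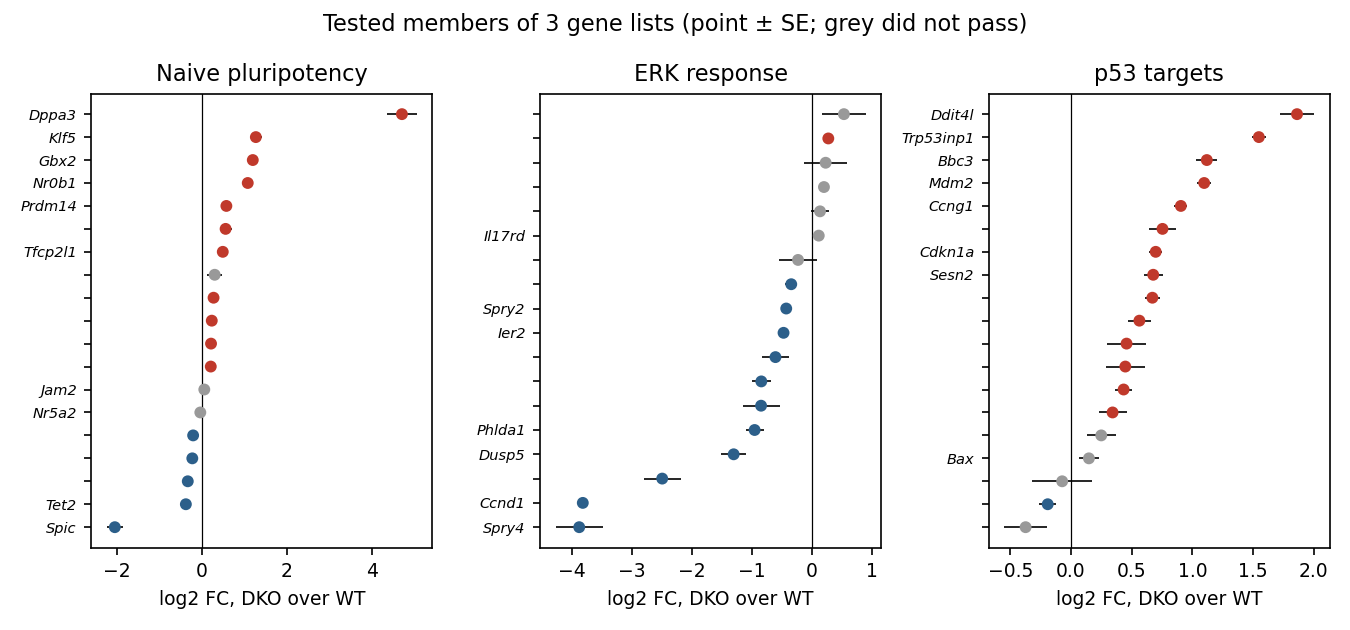
Log2 fold change ± SE of the libraries labelled DKO over WT for each tested member of the naive pluripotency, ERK response and p53 target lists, a point per gene, with the symbols of the genes the naming rule took. Trp53inp1 (1.55) and Mdm2 (1.10) stand to the right of 0 among the p53 targets, and Spry4 (-3.87) and Ccnd1 (-3.81) to the left among the ERK genes.

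Grhl2, which encodes the factor in the series title, had too few reads to be tested by edgeR: 8, 21, 26 and 35 counts in WT 1 to 4 and 2, 9, 2, 5 and 7 in DKO 1 to 5. That was 3.30 ± 1.58 CPM in WT and 0.796 ± 0.484 in the libraries labelled DKO (exact permutation p = 0.0159, BH 0.0238 over 3 low sums). Grhl3 rose by a log2 fold change of 1.02 ± 0.18 (edgeR adjusted p = 1.6e-05), and Grhl1 did not pass (-0.38 ± 0.24, edgeR adjusted p = 0.186).

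Cdh1, the adhesion protein E-cadherin, fell from 2724 ± 97.6 to 1390 ± 140 CPM (log2 fold change -0.97), on distal chromosome 8, where the median was -0.61. The keratin Krt8 (-2.35) and the claudin Cldn7 (-1.60) also fell, and Nectin2 (0.66), Pkp2 (1.05) and Cgnl1 (1.33), of cell junctions, rose, while Jup (-0.09) did not pass. Of 28 epithelial junction and keratin genes tested, 6 rose and 7 fell, also 6 and 7 adjusted over the list alone (camera adjusted p = 0.532). Among epithelial regulators, proteases and trafficking genes, Wnt7b (2.89) and Ezr (0.45) rose with Grhl3, and Ovol2 (-1.81), Rab15 (-1.22) and Rab11fip4 (-0.49) fell, while Elf3 (0.07) did not pass. Of 22 tested 6 rose and 7 fell, also 6 and 7 adjusted over the list alone (camera adjusted p = 0.853, downward although median and mean are 0.07 and 0.01).

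Of mesenchymal genes, Vim, an intermediate filament, rose from 145 ± 12.7 to 329.8 ± 10.9 CPM, with Fn1 (0.44) and Tgfb2 (2.78), while Snai1 (-1.56), Mmp14 (-0.99) and Sparc (-0.31) fell. Of 13 tested 5 rose and 7 fell, also 5 and 7 adjusted over the list alone (camera adjusted p = 0.853). The sum of the fibroblast list was 20.7 ± 1.67 CPM in WT and 10.1 ± 1.81 in the libraries labelled DKO (561 and 319 counts, exact permutation p = 0.00794, BH 0.0238). Col5a1 held 265 and 114 of these counts, while Pdgfrb had 36 and 37, Col1a1 18 and 19 and Col3a1 4 and 8, the last 3 picked after their values were seen. Its 2 tested members were Col5a1, which fell (-1.43), and Mmp2 (-0.57), which did not pass. That is 0 up and 1 down, also 0 and 1 adjusted over the list alone.

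Of mesendoderm genes, more fell than rose. Eomes (-2.24), a T-box factor, Bmp4 (-2.20), the VEGF receptor Kdr (-2.01), Evx1 (-2.55), Mixl1 (-1.61) and the Nodal antagonist Lefty2 fell, and Wnt3 (2.55) rose, while Nodal (-0.07) did not pass. Lefty2 was the most abundant, at 194.9 ± 17.2 CPM in WT and 67.0 ± 15.4 in the libraries labelled DKO. Of 8 tested members 1 rose and 6 fell, also 1 and 6 adjusted over the list alone. The list passed camera downward (adjusted p = 0.0125, and adjusted p = 0.156 with an estimated correlation, in a range of 0.00932 to 0.156). Most members lie under 20 CPM.

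In the trophectoderm list, Tfap2c rose from 66.3 ± 3.10 to 260.3 ± 31.9 CPM with Fgfr2 (3.29) and Tfeb (0.59), while its paralogue Tfap2a (-2.59) fell with Eomes, Msx2 (-2.11) and Ascl2. Of 11 tested 5 rose and 6 fell, also 5 and 6 adjusted over the list alone (camera adjusted p = 0.785). Primitive endoderm genes included rises of the laminins Lama1 (0.81) and Lamb1 (0.83), of Fst (0.71) and of Sox7 (4.17, from 0.148 to 2.99 CPM) and a fall of Dab2 (-2.97), while Lamc1 (0.01) did not pass. Of 8 tested 4 rose and 1 fell, also 4 and 1 adjusted over the list alone (camera adjusted p = 0.155). In the neuroectoderm list Gbx2 and Nes (0.79) rose and Olig2 (-1.27), Tubb3 (-1.19) and Neurod1 (-1.15) fell, with Tubb3 on distal chromosome 8. Of 8 tested 2 rose and 3 fell, also 2 and 3 adjusted over the list alone (camera adjusted p = 0.773), and the Neurod1 call was lost without WT 2, WT 4, DKO 2 or DKO 3 (edgeR adjusted p = 0.0555 to 0.0800).

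Among germline genes, Tex15 (1.62, on proximal chromosome 8) and Prdm1 (1.05) rose, and Stra8 (-2.06), Stk31 (-1.03), Rpl10l (-1.17) and Tuba3a (-0.92) fell. Of 13 tested 2 rose and 9 fell, and 2 and 10 adjusted over the list alone (camera adjusted p = 0.147, in a range of 0.0164 to 0.668 over 15 other camera fits). The list passed in 1 of these, without chromosomes 8 and Y, and not without 6, 8 and Y (0.101), both chosen after the data were seen. No gene of the list marking 2-cell-like cells had enough reads to be tested. The sum of that list was 4.22 ± 1.55 CPM in WT and 2.23 ± 0.679 in the libraries labelled DKO (114 and 70 counts, exact permutation p = 0.0238, BH 0.0238).

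More targets of p53, the transcription factor of the DNA damage response, rose than fell in the libraries labelled DKO. Trp53inp1 went from 81.6 ± 5.46 to 239 ± 7.66 CPM, Mdm2, the ligase that limits p53, from 137 ± 16.0 to 294 ± 4.47, and the cell cycle inhibitor Cdkn1a from 229 ± 10.6 to 372 ± 23.2. Ccng1 (0.91), Ddit4l (1.86) and the BH3-only gene Bbc3 (1.12) rose too, and Bax (0.15) did not pass. Of 19 tested members 14 rose and 1 fell (Ei24, -0.19), and 14 and 2 adjusted over the list alone. The list passed camera upward (adjusted p = 7.6e-07, and adjusted p = 0.156 with an estimated correlation, in a range of 1.55e-07 to 0.156).

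More ribosomal protein genes rose than fell, by small amounts. Rpl32 went from 773 ± 57.3 to 1147 ± 95.7 CPM, and Rpl22 (0.36), Rps10 (0.34), Rps21 (0.34) and Rpl31 (0.53) rose, while Rpl8 (0.08) did not pass. Of 74 tested members 41 rose and 2 fell, Rps29 (-0.45) and Rpl13 (-0.50), also 41 and 2 adjusted over the list alone. The list passed camera upward (adjusted p = 6.7e-07, and adjusted p = 0.156 with an estimated correlation, in a range of 1.2e-07 to 0.156). The share of all counts on these genes was 3.19% ± 0.0121 in WT and 3.79% ± 0.0906 in the libraries labelled DKO, and that on mitochondrial transcripts 1.42% ± 0.102 and 2.04% ± 0.290 (exact permutation p = 0.00794 for each, BH 0.0132). The mitochondrial share was 2.30% in DKO 4 and 2.41% in DKO 5, against 1.77% to 1.92% in DKO 1 to 3. Ribosomal protein genes have many processed copies, so single members are uncertain.

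Of cholesterol synthesis genes, more fell than rose. Mvd, a decarboxylase of the mevalonate pathway, went from 171 ± 16.2 to 88.1 ± 13.5 CPM and the demethylase Cyp51 from 173 ± 5.82 to 128 ± 18.5, and Fdps (-0.86) fell, while Msmo1 (-0.03) and Srebf2 (-0.05) did not pass. Of 20 tested members 1 rose (Sqle, 0.27) and 11 fell, also 1 and 11 adjusted over the list alone. The list passed camera downward (adjusted p = 0.00969, and adjusted p = 0.388 with an estimated correlation, in a range of 0.00348 to 0.388). Mvd lies on distal chromosome 8.

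In glycolysis, Ldha, which makes lactate, fell from 498 ± 16.4 to 209 ± 18.9 CPM, as did the lactate exporter Slc16a3 (-1.65), Pfkl (-0.88), Pfkp (-0.80) and Pkm (-0.44), whereas the glucose transporter Slc2a3 (0.93, on distal chromosome 6) rose and Slc2a1 (0.06) and Gpi1 (0.11) did not pass. Of 18 tested 3 rose and 8 fell, and 4 and 8 adjusted over the list alone (camera adjusted p = 0.0799), and the list passed downward without DKO 5 (adjusted p = 0.0371) and, in fits chosen after the data were seen, without chromosomes 8 and Y (0.0452) or 6, 8 and Y (0.00675), in a range of 0.00675 to 0.429 over 15 other camera fits of which 4 passed. Oxidative phosphorylation genes went both ways. Atp5c1 (0.33), Ndufa1 (0.37) and Sdha (0.22) rose and Uqcrc1 (-0.35), Cox4i1 (-0.33) and Ndufb7 (-0.30) fell, the last 2 on distal chromosome 8, while Atp5a1 (0.06) and Cox6c (-0.01) did not pass. Of 24 tested 9 rose and 4 fell, also 9 and 4 adjusted over the list alone (camera adjusted p = 0.403).

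Of the integrated stress response, Ddit4 (0.94) and Sesn2 (0.68) rose and Nupr1 (-1.85), Mthfd2 (-0.85), Trib3 (-0.54) and Shmt2 (-0.47) fell, while Asns (-0.02) did not pass. Of 17 tested 4 rose and 8 fell, also 4 and 8 adjusted over the list alone (camera adjusted p = 0.247). In the cell cycle list, Ccnd3 went from 526 ± 10 to 923 ± 73.1 CPM and Cdkn1b (0.94, on distal chromosome 6) rose, whereas the replication factors Mcm5 (-0.79, on distal chromosome 8) and Mcm2 (-0.43) and the mitotic kinases Aurka (-0.46) and Plk1 (-0.37) fell. Ccnb1 (-0.10) and Ccna2 (-0.09) did not pass. Of 24 tested 5 rose and 10 fell, and 5 and 11 adjusted over the list alone (camera adjusted p = 0.291, downward with a mean of 0.02).

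In the DNA methylation and demethylation list, Dnmt3l, Tet3 (-1.18), Tet2 (-0.37) and Uhrf1 (-0.30) fell and Uhrf2 (0.80) and Prdm14 (0.58) rose, while Dnmt1 (0.10) and Tet1 (-0.02) did not pass. Of 18 tested 3 rose and 5 fell, also 3 and 5 adjusted over the list alone (camera adjusted p = 0.853, downward with a median of 0.10). Of imprinted genes, Mest fell from 103 ± 2.71 to 27.6 ± 3.2 CPM with Phlda2 (-1.99), Dlk1 (-1.23), Peg12 (-1.40) and Slc38a4 (-0.64), and Plagl1 (0.81), Peg3 (0.59), Gnas (0.57) and Impact (0.45) rose. Of 25 tested 13 rose and 5 fell, also 13 and 5 adjusted over the list alone (camera adjusted p = 0.261, upward with a mean of -0.02 and a median of 0.27).

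By chromosome, genes of the mitochondrial genome and of the Y stood apart in the libraries labelled DKO. The median difference from WT in log2 CPM, taken with a prior count of 2, was 0.483 over 13 mitochondrial genes and -3.15 over 3 Y genes. By the log2 fold changes of edgeR, which are on another scale, Ddx3y (-5.12) and Uty (-4.41) fell and Gm47283 (0.76), in the part shared with the X, rose. The mitochondrial genome and the Y were the 2 chromosomes past a shift of 0.2 (exact permutation p = 0.00794 for each, the smallest possible, BH 0.0218), and chromosome 8 reached -0.177 (the same p). With genes of at least 10 CPM alone, chromosome 8 passed as well, at -0.231, and the Y stood at -2.003 over 2 genes. These were Ddx3y, which fell, and Gm47283, which rose, so that value lies between them and describes neither.

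Genes of chromosome 8 were higher on one side of a point beside Klf2 and lower on the other. The change point of the scan, which was added after the data were seen, lay between Tpm4 (starting at 72134975) and Rab8a (72161200). Taken per library in log2 CPM, with a prior count of 2, the 301 genes before it had a median 0.421 ± 0.0214 above genes off chromosomes 6, 8, Y and the mitochondrial genome in the libraries labelled DKO (1.34-fold), with 206 higher and 22 lower. The 363 genes after it had a median of -0.572 ± 0.0302 (0.673-fold), with 19 higher and 275 lower (SD, n = 5), with the sides divided at a point picked on this difference. Chromosome 6 changed between Gpr27 (99692679) and Rybp (100228565), from -0.203 ± 0.0120 over 326 genes to 0.347 ± 0.0182 over 233. A step passed on 14 of the 20 chromosomes scanned, and chromosomes 8, 6 and 4 each had a permutation p of 0.000999, the smallest that 1000 permutations can give (BH 0.00666), but neighbouring genes are not independent. The statistics were 28.9 and 14.1 on chromosomes 8 and 6 against 6.84 for the next, chromosome 4, and the medians of both sides differed by at most 0.237 on the other chromosomes that passed. The bootstrap interval of the chromosome 8 step ran from 71374123 to 72319033, the start of Klf2, over 26 genes. Klf2 starts beyond the change point but within this interval, so its side is not settled. Its log2 fold change (0.42) was 1.03 above the median of edgeR's log2 fold changes after the point (-0.61, relative to the same other genes) and close to that before it (0.41). Among genes named in other groups, Asns, Evx1, Mest, Stra8, Stk31, Mthfd2, Tet3 and Mcm2 lie on proximal chromosome 6. Rpl32 and Tuba3a lie on distal 6, Msmo1 and Sfrp1 on proximal 8 and Rpl13 on distal 8. The tally does not cover every named gene. Genes of chromosomes 6 and 8 made up 15.4% of all calls and 10.3% of tested genes.

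**Figure D5:**
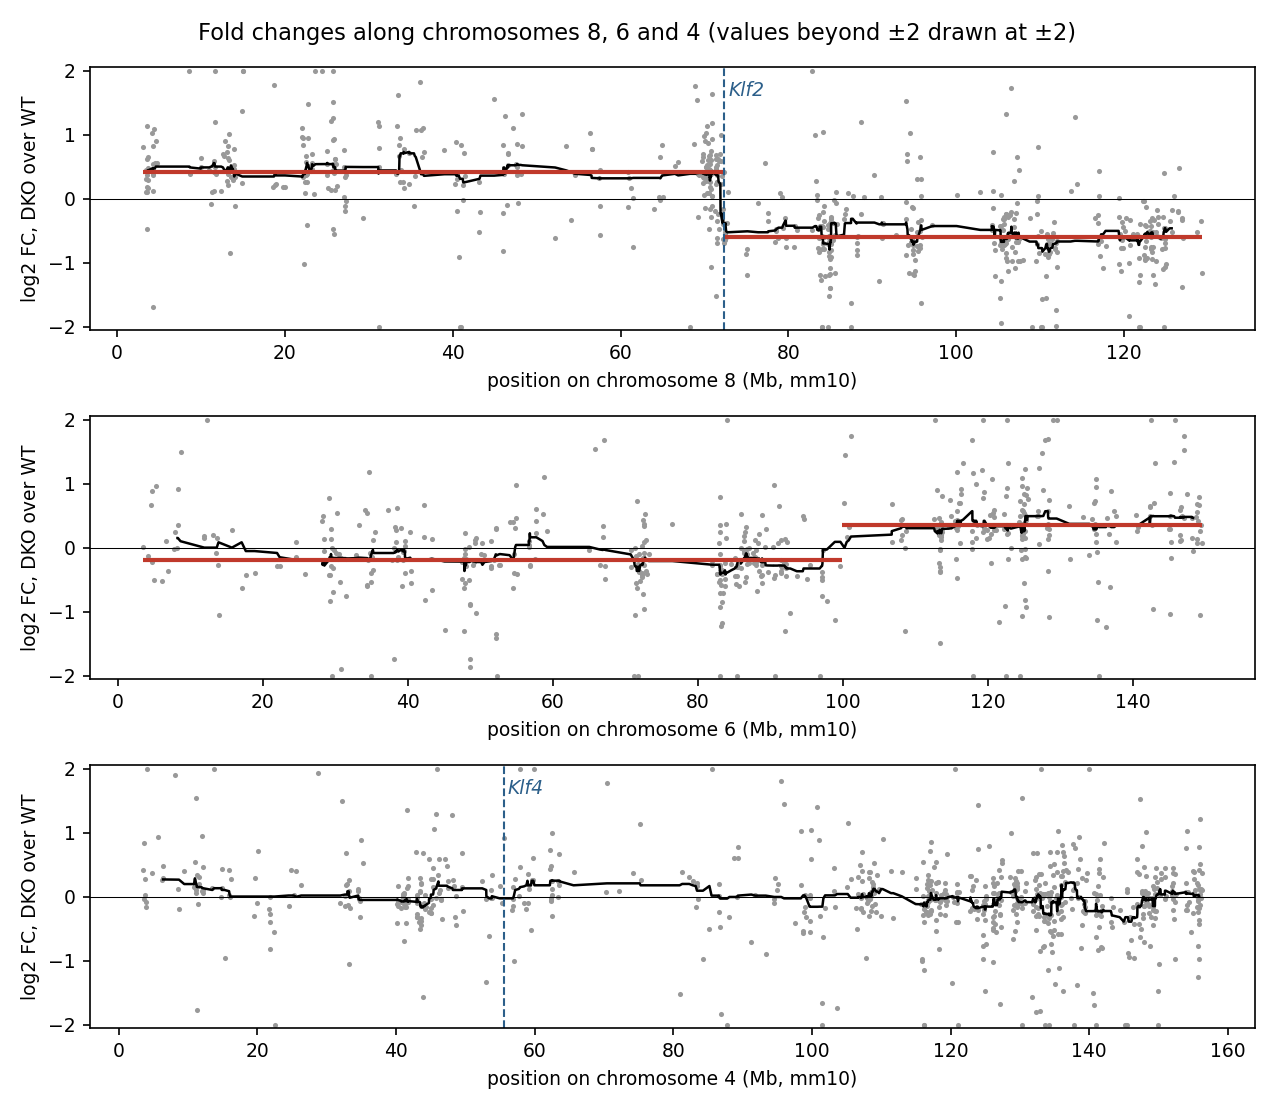
Log2 fold change of the libraries labelled DKO over WT along chromosomes 8, 6 and 4, a grey point per gene by position in Mb, a black running median of 25 genes, red medians on each side of the change points of chromosomes 8 and 6, and dashed lines at Klf2 and Klf4. As medians of these log2 fold changes, not set relative to other genes, chromosome 8 changes from 0.42 to -0.60 beside Klf2 and chromosome 6 from -0.19 to 0.35, while chromosome 4 stays near 0 around Klf4.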

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

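Each group's highest and lowest library was measured by its gap to the nearest other library, as a share of the group's range, in 374 groups of values, and no test here was chosen after its result was seen. In 25 groups, or 6.68%, the gap passed Dixon's limit, where chance gives about 5%. These were 13 WT and 12 DKO groups, with WT 2 the library apart in 7 and DKO 3 in 5.

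WT 2 was the lowest WT library for Klf4, at 776 CPM against 863 to 878 (gap 0.852), and also for Fgf10 (0.950), Sparc (0.838), Gpi1 (0.914) and Ddit4l (0.843). It was the highest for Ccdc141 (0.923) and Nes (0.889). WT 1 was the highest WT library for Mybl2 (0.856) and Fgfr2 (0.866) and the lowest for Uhrf1 (0.844). WT 3 was the highest for Mmp14 (0.830) and the lowest for Tfap2a (0.978) and Sdha (0.877).

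DKO 3 was the lowest library labelled DKO for Lefty2, at 40.2 CPM against 71.3 to 79.0 (0.804), and the highest for Foxd3 (0.748), Sparc (0.733), Lamc1 (0.731) and Aurka (0.718). DKO 1 was the highest for Pfkl (0.731) and the lowest for Crxos (0.764). DKO 2 was the lowest for Nr5a2 (0.720), DKO 4 the highest for Ascl2 (0.71) and Pfkp (0.736), and DKO 5 the lowest for Lama1 (0.780) and Socs2 (0.715).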

How the results depend on the processing

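The fits without chromosomes 8 and Y, without 6, 8 and Y, without ribosomal genes in the adjustment, and the chromosome medians centred on all libraries were chosen only after the data were seen. Klf2 and Klf4 stayed higher in the libraries labelled DKO in every fit that held them, at 0.41 to 0.43 and 0.87 to 0.95 with 1 library left out. Counts of genes lay between 2560 and 2849 higher and between 2661 and 2880 lower with 1 library left out, and every call shared with another setting kept its direction. DESeq2 made 5361 calls and limma-voom 5689, and the scalings gave 49.2% to 50.9% of calls as higher. With no filter 24485 genes were tested and 1164 fell at least 2-fold. With at least 5 CPM in 4 libraries 9698 were tested, and 293 rose and 418 fell at least 2-fold. The main fit tested 11893, with 492 and 720, so a larger share of the 2-fold calls was lost than of the genes tested. Under that filter mesendoderm had under 5 members and no list test.

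Lists moved most with the kind of test. With an estimated correlation camera passed 0 lists up and 0 down, although naive pluripotency, mesendoderm, ERK response, p53 targets and ribosomal proteins had an unadjusted p under 0.05, and fry passed 8 and 12. Without chromosomes 8 and Y, 5 lists passed downward, with germline genes and glycolysis added, and the cause was not tested. With 1 library left out, 2 to 3 lists passed upward and 3 to 4 downward. Naive pluripotency passed in 8 of 9 such fits, narrowly without WT 1 (adjusted p = 0.04997) and not without WT 2 (0.0530), and had an adjusted p of 0.0730 with the filter of 5 CPM.

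Genes that did not pass and lay near 0 changed sign, for a cause not tested: with sample weights Lamc1 (-0.0101) and Stat3 (-0.0175), and in thinned libraries Lamc1 (-0.0041). With 1 library left out they ran from -0.0594 to 0.0354 for Lamc1, -0.0317 to 0.054 for Stat3, -0.1047 to 0.0238 for Msmo1, -0.05 to 0.0112 for Cox6c, -0.0576 to 0.0074 for Rif1, -0.0355 to 0.0083 for Asns, -0.1044 to 0.0225 for Srebf2 and -0.0607 to 0.0057 for Nr5a2. Among named genes and alternatives 4060 values kept sign and side of the threshold, 20 changed sign, 13 newly passed and 4, all of Neurod1, no longer passed.

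With the replicate number as a block, on 8 libraries, 2699 genes rose and 2798 fell, against 2602 and 2661 in those 8 libraries without it, and no list call differed between these fits. Glycolysis passed downward in both (adjusted p = 0.0424 and 0.0371), so that call came with leaving out DKO 5. Msmo1 changed sign in both (0.0164 and 0.0238). Same-numbered libraries deviated together by r = 0.069, 0.010, 0.070 and 0.034 across genes, none over the limit of 0.1. The numbers were therefore not taken to pair the libraries. Differently numbered libraries ran from -0.057 to 0.052, so a weak pairing is not excluded. In libraries thinned to the smallest total, 2793 genes rose and 2803 fell. Grhl2 and the list of 2-cell-like cells had too few reads for the gene test.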

Other observations

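Chosen only after their results were seen were the tests on Klf2 and Klf4, the scan for change points with the tests that follow it, and the comparison of gene families. Those on the Y genes, on the whole of chromosome 8 and on other divisions of the libraries were not.

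Of 124 families of at least 10 tested genes that share the start of their symbol, the Rps family passed camera upward (28 up and 4 down of 62, adjusted p = 0.0121, and adjusted p = 0.917 with an estimated correlation), which overlaps the ribosomal protein list. It also holds genes outside that list, such as Rps6kl1 (3.27), Rps6ka4 (-1.84) and Rps6ka6 (0.63). The Rpl family, with 22 up and 5 down of 73, did not pass camera (adjusted p = 0.169). Proteasome genes (Psm) held 2 rises and 13 falls among 38 (adjusted p = 0.169) and RNA polymerase genes (Polr) 1 and 11 among 28 (adjusted p = 0.295). Zinc finger genes (Zfp) held 86 rises and 33 falls among 310 (adjusted p = 0.295). None of the last 3 passed. Pou5f1, a core factor of pluripotency, had 23.9 ± 0.552 CPM in WT and 21.5 ± 3.16 in the libraries labelled DKO, and the housekeeping gene Gapdh 3.05 ± 0.767 and 3.38 ± 1.90, although both are usually abundant transcripts of these cells. Gm42418 took 6.11% to 8.11% of each library's counts.

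Klf2 and Klf4 had more reads in the libraries labelled DKO. A wrong label on a single library is argued against, since 0 of the 9 libraries lay nearer to the other group. Exchanged labels of the groups stay open: the lower of both genes in WT was 53.2% of its level in the other group, so neither group lacks the transcripts. A further candidate explanation, which the gene counts cannot place, is that transcripts of the disrupted alleles are still made and counted, and the lower of both stood at 134% of WT. A biological rise of the transcripts was not tested. Neither was a link of Klf2 to the shift of chromosome 8 genes. Its log2 fold change (0.42) was close to the median before the step (0.41), but its side of the step is not settled. Klf4 lies on chromosome 4.

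Genes of the Y fell in the libraries labelled DKO. Ddx3y went from 708 counts in all to 23 (2.83% of its WT level in CPM) and Uty from 3.76 to 0.161 CPM (4.28%), while Eif2s3y, at 36 and 13 counts, kept 31.0%. Lower depth is argued against, since 0.334% of other genes at 20 to 35 CPM in WT fell 8-fold. Loss of the Y chromosome in the cells behind these libraries may explain the falls of Ddx3y and Uty. It predicted an 8-fold fall of every such gene with at least 20 WT reads, and 2 of the 3 fell that far. Eif2s3y met that minimum and did not, so the prediction was not met in full. Its reads were few, and the explanation stays open.

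Chromosome 8 was higher on one side of a step near Klf2 and lower on the other. A copy number difference of the whole chromosome is argued against, since the highest median of 4 equal parts along it was 0.454. The share of genes under 0 over the whole chromosome cannot decide whether a few strongly changed genes explain it, since rises and falls offset each other there. It was 6.42 percentage points above that elsewhere, with a 95% interval from 51.2% to 59.0% against 48.7%. Beyond the step the excess was 38.6 points, but that side was picked on the same values and cannot test this. In parts 3 and 4 of the 4 equal parts, set without regard to the step, 84.3% and 91% of genes lay under 0. In parts 1 and 2 the share was 12% and 33.1%. The medians of parts 1 to 4 were 0.454, 0.326, -0.602 and -0.625, each with a 95% bootstrap interval over genes that left out 0. A few strongly changed genes are thus argued against in all 4 parts. A difference in the number of copies with an end near Klf2 is a candidate explanation that stays open. Of 625 candidate positions 9 lay as near to Klf2 as the step (171 kb), but that place prompted the hypothesis and cannot test it, and over low, middle and high expressed genes the medians ran from 0.362 to 0.54 before the step and from -0.641 to -0.398 after it. No DNA was measured.

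The counts were compared over other divisions of the 9 libraries into 4 and 5, 100 of the 126 with the real one among them. The real counts of 2837 higher and 2852 lower genes were reached in 1 division each, with 1436 and 1017 the highest of the others. The count of 492 at least 2-fold higher was reached in 3 (highest other 512) and that of 720 lower in 1 (132). The list counts of 3 up and 3 down were reached in 4 and 3 divisions (highest other 3 and 3). Among the divisions drawn, under 5% reached each count. Over all 126 that share stays open for the list counts and for the 492 genes. Other divisions reached them, and those not drawn could bring the share to 5% or more. Divisions drawn that exchanged 1 to 3 libraries gave 0 called genes, so the gene counts were largely fixed once the groups differed. They cannot tell the genotype from any other difference between the groups. The highest other counts of genes came from divisions of the 4 WT libraries with 1 DKO library against the remaining 4, a structure close to the real one.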
